A study of Pyrus x bretschneideri with 5 samples.

How the data were processed

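Messenger RNA of fruit of the Chinese white pear cultivar Dangshansuli was profiled as short sequence tags at 5 numbered developmental stages, with 1 library per stage. Each deposited file lists the tags of 1 library, and each tag is 21 bases long and begins with CATG, the recognition site of the restriction enzyme NlaIII. The extraction text of the labels describes fragmented poly(A) RNA with random priming, a procedure that would not by itself place CATG at the start of each read, so the tag construction is known only from the values of the files. The tissue and source fields of the labels list several organs for all 5 libraries, whereas the titles, the stage field and the extraction text speak of fruit. The libraries are described here as fruit on that basis.

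The authors deposited 2 values per tag. The first is a copy number, a whole-number count of the tag in the library, per the file headers. The second is a value named TPM, per the file headers. It was checked against the counts and equalled the count scaled to the file's own total, within rounding, for each listed tag. It is therefore a share of tags with no correction for transcript length. The smallest deposited count in each file was 2, and a tag missing from a file was taken to have had at most 1 copy there. This is an assumption, because the base caller, tag filter and software used by the authors are not given in the sources used here, and a filter on something other than the copy number could have removed a tag with more copies.

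The tags were not matched to genes. The reference table used here holds gene symbols and positions of the Pyrus bretschneideri v1 assembly without sequences, and the files pair no tag with a gene, so tags are reported by sequence and the 27 gene lists chosen for this tissue were not tested. No tag sequence is called by a gene name here. A gene can give more than 1 tag, and near-identical gene copies can share a tag, so a number of tags is not a number of genes. Genomic positions and annotations of the tags are not reported for the same reason.

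Everything below was computed from the counts. Levels are copies scaled to the library total, abbreviated TPM as in the file headers. Total counts ranged from 5602344 to 5987439 copies, so that 2 copies, the smallest listed count, corresponded to 0.334 to 0.357 TPM. Comparisons used the 21521 tags with at least 10 TPM in at least 1 library, out of 253303 distinct tags. The ratio of 2 libraries was given with an exact conditional (Clopper-Pearson) 95% interval, in which a tag missing from a file was given 1 copy. A fold against such a library is printed only as a lower bound, the lower end of that interval, and holds only under that assumption. These intervals and bounds cover counting error only, since copies may include PCR duplicates and since no stage has a second library.

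With 1 library per stage no test between stages was possible on replicate spread. The 4 adjacent steps and the last stage against the first were therefore described by a size rule: at least 4-fold apart, with the counting interval wholly beyond 2-fold. Such counts compare libraries, not stages. The only test was of a trend, with the stage number as 1 numeric term over the 5 libraries (edgeR 4.0.16, quasi-likelihood, TMM scaling, Benjamini-Hochberg adjusted p under 0.05). That leaves 3 residual degrees of freedom, its spread is the deviation of the libraries from a line, and the stages are treated as evenly spaced. Tags named in the text are the 3 highest and the 3 lowest of each comparison, ranked by the interval bound nearest to 1 among tags with at least 50 TPM in either library, and the 3 most abundant of each library. The size rule, the trend test, the gene lists and the rule for named tags were fixed before the data were examined, and other named tags are said to be chosen afterwards.

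Both procedures were tested on simulated data with 200 changed tags among the 21521. For the trend, with a dispersion of 0.1, the test recovered 36 of 100 tags with a slope of 0.5 (log2 per stage) and 100 of 100 with a slope of 1, and called 3 of 21321 unchanged tags. With a dispersion of 0.27 it recovered 1 of 100 and 45 of 100, and called 0 of 21321 unchanged tags. For stage 3 against stage 2, the size rule recovered 100%, 90.5% and 82.5% of 8-fold changes at dispersions of 0, 0.1 and 0.27, and passed 0, 142 and 1820 of 21321 unchanged tags. At 0.27 it passed 1867, 1871, 1809 and 1888 unchanged tags for stages 2 against 1, 4 against 3, 5 against 4 and 5 against 1. The last dispersion is close to the 0.273 estimated around the trend, which also contains departures from a line.

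Alternatives were TMM and DESeq2 size factors (DESeq2 1.42.0), other filters, a 2-fold rule, the DESeq2 Wald test, limma-trend (limma 3.58.1) on log2(TPM + 1), and leaving out each library. Alternatives added after seeing the data merged a tag into another that differed at 1 base when it had at most 2% of its copies, left the 26 tags that were among the 10 most abundant of any library out of the totals, gave missing tags 0.5 copies, and removed differences between classes of GC content. Computations used Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) and R 4.3.3.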

Results

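The study profiled transcripts of Chinese white pear fruit during development and maturation. Tags were counted in 5 libraries, 1 for each of the developmental stages numbered 1 to 5 in the labels, which give no days. The libraries held 5779213, 5602344, 5771830, 5987439 and 5968618 tag copies from stage 1 to stage 5, and 127209, 130176, 128372, 125656 and 122997 distinct tags. Of 253303 distinct tags, 55967 were listed in all 5 libraries, and these carried 91.5% to 93.9% of the copies of a library. No stage had a replicate, so intervals describe counting error alone, and lower bounds of a fold take a tag missing from a list to have had at most 1 copy, and the depth was similar enough that 1 copy weighed nearly the same in each library.

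The most abundant tag differed between early and late fruit. CATGTTGTGTGATGAAATGAA was the most abundant tag at stage 1 (54286 TPM, exact Poisson 95% interval 54097 to 54477) and stage 2 (41632 TPM), and stood at 13386, 6311 and 3539 TPM at stages 3, 4 and 5. CATGTTAGTGGCCTTGTGATG was at 77.5 TPM (70.5 to 85.0) at stage 1, 1839 TPM at stage 2 and 8852 TPM at stage 3, and became the most abundant tag at stage 4 (52517 TPM, 52333 to 52700) and stage 5 (36644 TPM). CATGAAGTAGTAGTATTTATA was among the top 3 in all 5 libraries, led at stage 3 with 40267 TPM, reached 46657 TPM at stage 4, and was lowest at stage 2 with 14253 TPM. CATGCATATGTATTTTTGGGA was in the top 3 at stage 5 with 9769 TPM, against 224 TPM at stage 1 and 171 TPM at stage 2. CATGTTGTGTGTGATGAAATG was in the top 3 at stage 1 (9122 TPM) and stood at 422 TPM at stage 5. CATGCAGATTTTTGTCAAGAC was in the top 3 at stage 2 (8528 TPM) and at 1898 TPM at stage 5, and CATGTAAATAGTGTACCTTTT was in the top 3 at stage 3 (9113 TPM) with 3369 TPM at stage 1 and 3235 TPM at stage 5. The 10 most abundant tags of a library took 11.4%, 9.65%, 10.5%, 13.7% and 11.5% of its copies from stage 1 to stage 5.

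**Figure D1:**
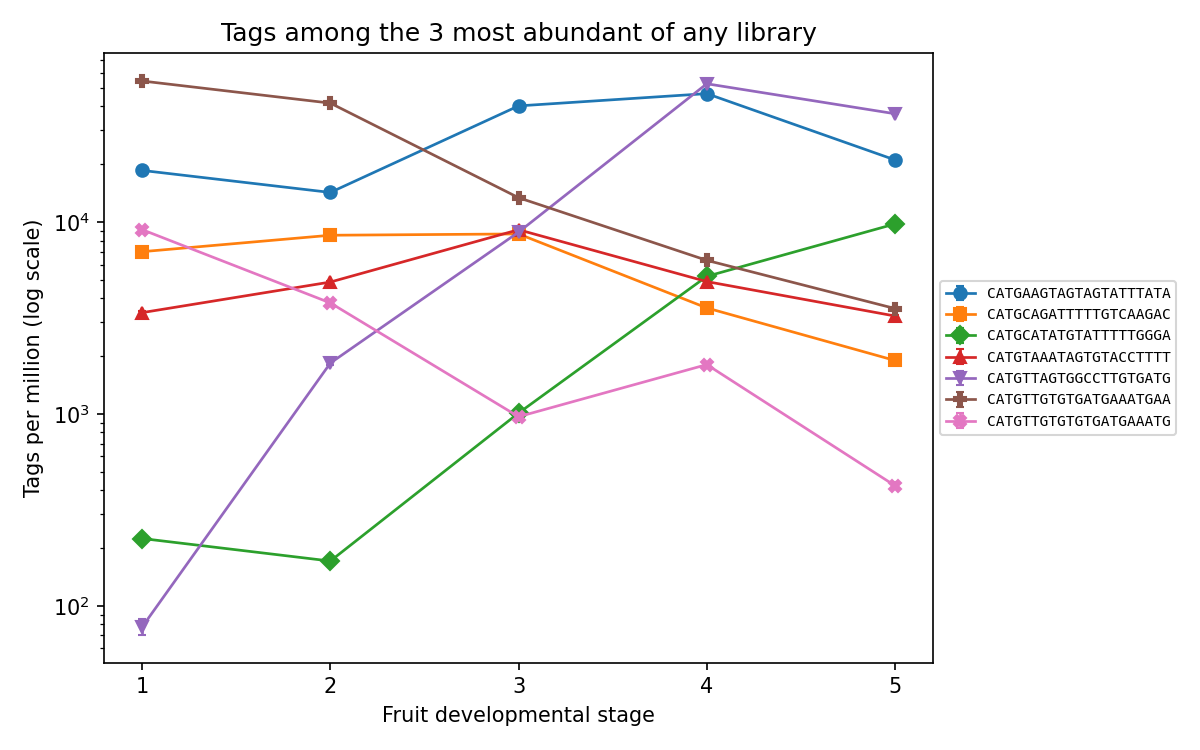
Level of the 7 tags that were among the 3 most abundant of any library, in TPM on a log axis, against the fruit developmental stage. Points are single libraries and bars are exact Poisson 95% intervals, mostly smaller than the points. CATGTTAGTGGCCTTGTGATG went from 77.5 TPM at stage 1 to 52517 TPM at stage 4, and CATGTTGTGTGATGAAATGAA from 54286 TPM at stage 1 to 3539 TPM at stage 5.

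The order of the stages was visible in the distance between libraries. Across 21521 tags at 10 TPM or more in some library, Spearman's rho was 0.866 between stages 1 and 2, 0.663 between stages 2 and 3, 0.752 between stages 3 and 4 and 0.798 between stages 4 and 5. It was 0.554, 0.377 and 0.299 between stage 1 and stages 3, 4 and 5. The median absolute log2 ratio was 0.45 between stages 1 and 2 and 1.29 between stages 1 and 5. These coefficients are across tags, which are not independent replicates, and no p-value was taken from them.

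**Figure D2:**
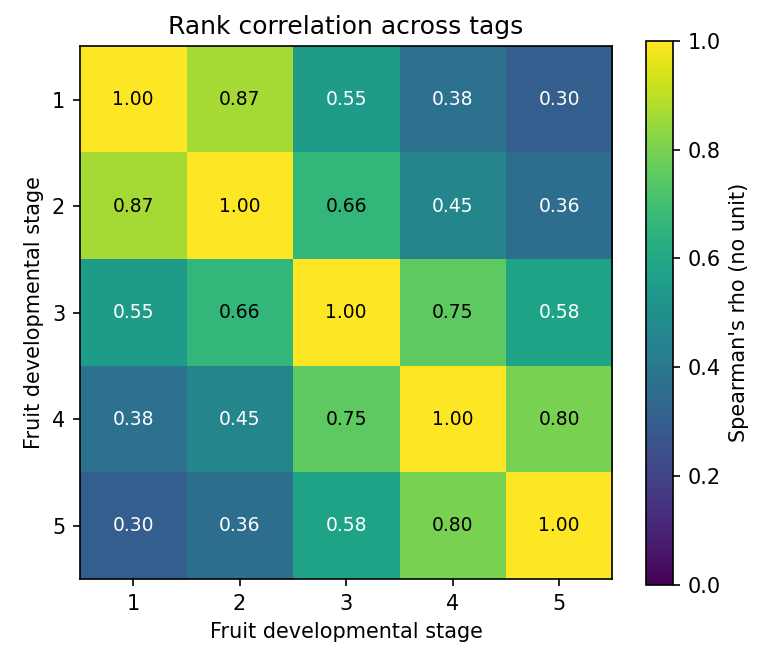
Spearman's rho across 21521 tags for each pair of the 5 libraries, with the developmental stage on both axes and the coefficient, without unit, as colour and number. Values fall with the number of stages between libraries, from 0.866 for stages 1 and 2 to 0.299 for stages 1 and 5.

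Between stages 1 and 2 fewer tags differed than at any other step, and more were higher than lower. CATGGTTTTTCTAGAATCTAG was at 128 TPM (716 copies) at stage 2 and was listed in no other library, a level at least 132-fold above stage 1. CATGGTGTATCAATAATAAAA was at 117 TPM at stage 2 and not listed at stage 1, at least 121-fold higher. CATGTGCTGGACAATTATTAC was at 86.7 TPM against 2 copies at stage 1, a ratio of 251 (counting interval, 69.0 to 2076). On the lower side, CATGAATAAAAATGCAATGAG was at 56.4 TPM at stage 1 and had 2 copies at stage 2, a 158-fold difference (43.4 to 1310), but was again at 41.1 TPM at stage 4. CATGTAACGTGCCTAAAAAAA was 44.2-fold lower (29.0 to 70.8) and CATGTGCACTTCCAAAAAAAA was 41.0-fold lower (27.4 to 64.2), from 174 and 175 TPM at stage 1. In all, 466 tags (2.17%) were higher and 225 (1.05%) were lower at stage 2 by the size rule, with no replicate check. That is fewer than the 1867 of 21321 unchanged tags that passed the rule in simulation with a dispersion of 0.27. If it held for all tags, a dispersion of 0.27 would thus be too high for these 2 libraries. That dispersion is close to the 0.273 found around the trend, which also contains departures from a line. At a dispersion of 0.1, 153 unchanged tags passed. Without replicates, the dispersion between libraries of the same stage is not known.

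The step from stage 2 to stage 3 had the most differing tags of the 4 adjacent steps. The 3 most strongly higher tags were near absent at stage 2 and among the abundant tags at stage 3. CATGTAGAGTGAGCGTTAACT had 2 copies at stage 2 and 15830 at stage 3 (2743 TPM), a ratio of 7683 with a counting interval from 2126 to 63440. CATGTAATAATCAATGAAATT was at 3369 TPM, 3775-fold higher (1617 to 11630), and CATGTAATAATCCCATCTAAT was at 2093 TPM, 2931-fold higher (1144 to 10760). CATGGTTTTTCTAGAATCTAG, the tag seen at stage 2 alone, was at least 132-fold lower at stage 3. CATGTGGAAAGTGTCCGGTTC was at 197 TPM at stage 2 and 0.52 TPM at stage 3, 380-fold lower (130 to 1845), and CATGAACTGGGATGACGTGGG was at 235 TPM and 0.866 TPM, 271-fold lower (116 to 837). By the size rule 1077 tags (5.00%) were higher and 1666 (7.74%) lower. The lower tags together held 116410 TPM at stage 2 and 17510 TPM at stage 3, and the higher tags held 10539 TPM at stage 2 and 90813 TPM at stage 3. At the dispersion of 0.27, 1820 of 21321 simulated unchanged tags passed the rule, and 142 passed at 0.1.

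From stage 3 to stage 4, more tags were lower than higher, and the strongest lower tags had been present since stage 1 or stage 2. CATGGACAATTCAAAGTCCAT was at 232, 244 and 96.3 TPM at stages 1, 2 and 3 and was listed at neither stage 4 nor stage 5, at least 103-fold lower. CATGATGTATACTGTGAGAAA was at 446, 707 and 197 TPM at the first 3 stages and at 0.835 TPM at stage 4, 236-fold lower (101 to 729). CATGGTGTATCAATAATAAAA was at 117 TPM at stage 2, 4101 TPM at stage 3 and 40.3 TPM at stage 4, 102-fold lower (89.7 to 116). The 3 most strongly higher tags were nearly confined to stage 4. CATGAACCGGGGCATCGACGT (195 TPM, at least 202-fold) and CATGGGGACCATCATTGGTGC (108 TPM, at least 111-fold) were listed in no other library, and CATGGATATGAATACATATCC was at 117 TPM against 3 copies at stage 3, a ratio of 225 (76.5 to 1092). The size rule gave 750 higher tags (3.48%) and 1300 lower tags (6.04%), and 290 of the lower tags were not listed at stage 4, while 34 of the higher tags were not listed at stage 3. At the dispersion of 0.27, 1871 of 21321 simulated unchanged tags passed the rule, close to both counts together. That dispersion was too high for stage 2 against stage 1, so this closeness does not show that the calls are noise. At 0.1, 133 passed.

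From stage 4 to stage 5, the 3 most strongly lower tags were ones abundant at stages 3 and 4. CATGTAGAGTGAGCGTTAACT (2161 TPM at stage 4), CATGTAATAATCAATGAAATT (1210 TPM) and CATGTAATAATCCCATCTAAT (1103 TPM), the same tags that led the step into stage 3, were not listed at stage 5, and were at least 2314-fold, 1296-fold and 1181-fold lower. CATGGTTTTTTTCTAGATTCT was at 2.51 TPM at stage 4 and 1254 TPM at stage 5, 501-fold higher (303 to 895). CATGCCTGCCTTTAACTTAAA was at 3.67 TPM and 557 TPM, 152-fold higher (100 to 242). CATGGTTTTTTTTCTAGATTC was at 92.1 TPM at stage 5, listed nowhere else, and at least 98.6-fold higher. Apart from an added T in its run of T, this last tag had the bases of the first higher tag named here. It had 550 copies at stage 5 against 7486 of that tag, which had 41, 8, 0 and 15 copies at stages 1 to 4. At such counts its absence elsewhere cannot show a separate transcript, and its rising trend, given below, has the same limit. The tests of pairs did not cover added bases, so its origin was not tested. By the size rule 435 tags (2.02%) were higher and 881 (4.09%) lower at stage 5. Together they were fewer than the 1809 of 21321 simulated unchanged tags that passed at the dispersion of 0.27. A dispersion of 0.27 for all tags would thus be too high for this pair of libraries as well. At 0.1, 128 passed.

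Over the whole span, stage 5 against stage 1, more tags passed the size rule than at any adjacent step. CATGTTTCATTACGTACAGTG had 3 copies at stage 1 and 1081 TPM at stage 5, 2083-fold higher (713 to 10110), with most of the difference after stage 3. CATGTTCTTAAAGGGGAAGGG was 1626-fold higher (635 to 5969) at 1125 TPM and was already at 698 TPM at stage 3. CATGTCAATTATGTAAGTATT was not listed at stages 1 and 2 and was at 604 TPM at stage 5, at least 626-fold higher. CATGTGGAAATTCGTACGTAA was at 2785 TPM at stage 1 and 1.34 TPM at stage 5, 2078-fold lower (1054 to 4813). CATGTATTGCAAAGTTGTGAA (791 TPM) and CATGCGATTGTATTTCCTGGC (755 TPM) were not listed at stage 5 and were at least 847-fold and 808.5-fold lower. In all, 3021 tags (14.04%) were higher and 3788 (17.6%) lower. The higher tags held 25283 TPM of the stage 1 library and 304860 TPM of the stage 5 library, and the lower tags 348060 TPM and 27205 TPM. In simulation at the dispersion of 0.27, 1888 of 21321 unchanged tags passed, and 153 passed at 0.1.

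**Figure D3:**
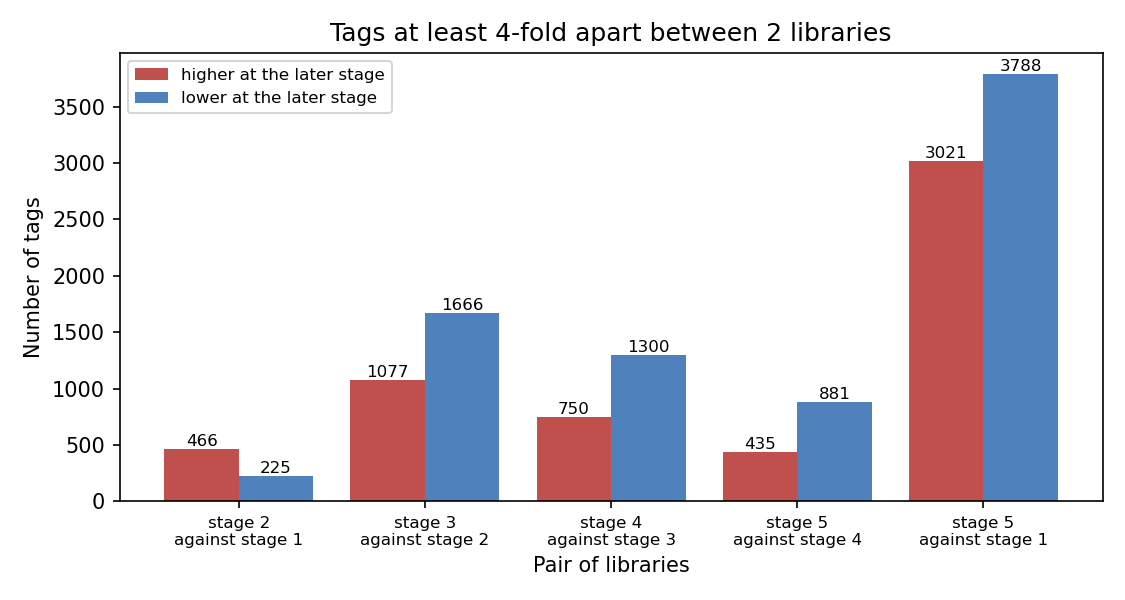
Number of tags at least 4-fold apart between 2 libraries with a 95% counting interval beyond 2-fold, for the 4 adjacent steps and for stage 5 against stage 1, with tags higher at the later stage in red and lower in blue. The step from stage 2 to stage 3 has 1077 higher and 1666 lower tags, and the step from stage 1 to stage 2 has 466 and 225.

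Tags past the test of a trend with stage number included several of the most abundant of the fruit. In the edgeR quasi-likelihood test, CATGTTAGTGGCCTTGTGATG rose by a log2 slope of 2.27 per stage (adjusted p = 0.0284) and CATGCATATGTATTTTTGGGA by 1.46 (adjusted p = 0.0173), and CATGTTTCATTACGTACAGTG, the leading tag of stage 5 against stage 1, by 3.06 (adjusted p = 0.0142). CATGTTGTGTGATGAAATGAA fell by 1.12 per stage on the log2 scale (edgeR adjusted p = 0.0183), CATGTTGTGTGTGATGAAATG fell by 1.02 (edgeR adjusted p = 0.028), and CATGTGGAAATTCGTACGTAA fell by 2.75 (edgeR adjusted p = 0.0147). Some tags with a peak at stage 3 or 4 did not pass, among them CATGTAGAGTGAGCGTTAACT (edgeR adjusted p = 0.54) and CATGAAGTAGTAGTATTTATA (edgeR adjusted p = 0.619). Of 21521 tags tested, 1524 rose and 2611 fell, 19.2% in all. Of these, 1316 and 1963 were listed in all 5 libraries, and 2 of the rising tags, CATGGTTTTTTTTCTAGATTC (550 copies) and CATGTTCTTGGGGAAAAAAAA (104 copies, chosen after its values were seen), were listed at stage 5 alone. With 1 library left out, at 2 residual degrees of freedom, edgeR called 0 tags without stage 4 and 0 without stage 5, 356 rising and 1238 falling without stage 1, 291 and 945 without stage 2, and 1703 and 2951 without stage 3. The tags at an unadjusted p under 0.05 numbered 6208, 5854, 8531, 6477 and 6614 without stages 1, 2, 3, 4 and 5, against 8146 with all 5 libraries.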

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

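Tests that merged near-identical tags, left the most abundant tags out of the totals, changed the value of missing tags or removed GC classes were chosen after seeing the data. Under TMM scaling, DESeq2 size factors, merged tags, totals without the top tags and 0.5 copies for missing tags, the 50 counts of the size rule stayed within 1.5 times those reported, and the log2 ratios of the named tags kept their direction and stayed within their counting intervals in 90 of 90 checks of scaling. The kept direction tested little, because the named tags were chosen for extreme ratios and the TMM and DESeq2 factors lay between 0.888 and 1.07. TMM lowered the median log2 ratio of stage 5 against stage 1 from 0.14 to -0.05 and DESeq2 factors moved the share of higher tags at that span from 44.4% to 37.6%. Filters and the fold limit set the size of the counts, because they set how many tags can pass. For stages 2 against 1, 3 against 2, 4 against 3, 5 against 4 and 5 against 1 in turn, no filter gave 958, 2013, 1444, 1173 and 6691 higher tags and 547, 3394, 2231, 1585 and 8255 lower tags. A filter at 50 TPM gave 155, 355, 183, 115 and 825 higher and 56, 530, 449, 301 and 1192 lower tags. The 2-fold rule gave 2283, 3663, 3144, 2524 and 6678 higher and 1411, 3840, 3536, 3528 and 6096 lower tags. For stage 5 against stage 1 it turned the balance, from more lower tags under the 4-fold rule to more higher tags. Spearman's rho for the same pairs was 0.6535, 0.5954, 0.632, 0.6468 and 0.4637 with no filter and 0.8394, 0.5152, 0.6783, 0.7616 and 0.0524 with the 50 TPM filter, and Pearson's r of log2 values was 0.9006, 0.6959, 0.7855, 0.8405 and 0.3365; the cause was not tested. For the trend, 4263 tags rose and 7511 fell with no filter (253303 tags tested), 682 and 863 with the 50 TPM filter (5419 tags tested), and 3066 and 4363 in the DESeq2 Wald test. limma-trend called 2452 rising tags, and the other scalings and the GC correction left both counts within 1.5 times. Leaving out 1 library gave 0 to 1703 rising and 0 to 2951 falling tags, with 2 residual degrees of freedom. Alternatives that need transcripts (only the last CATG site, shared tags, 1 mismatch) and all work on gene lists were not run because tags were not matched to genes, and the one on single-copy tags was not run because no file lists any. No paired analysis was possible because each stage had 1 library. Depth limits tags near 10 TPM, about 56 to 60 copies, to wide ratios, and the level of a missing tag rests on the assumption that it had at most 1 copy.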

Other observations

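The tests of sequencing errors, of composition and of poly(A) tails, and that of profiles without runs of A, were chosen after results of earlier tests were seen, and the patterns of pairs, of tags ending in A and of runs of stages were themselves chosen after the data were seen. The tests on GC content were set before their results but after the mean GC content of each library was known. Tags named here and not in the comparisons were chosen after their values were seen. Among 5419 tags at 50 TPM or more in some library, 56 were concentrated in stages 3 and 4, with each other stage at least 16-fold below the peak. Together they stood at 9.86 and 87.3 TPM at stages 1 and 2, at 17452 and 11180 TPM at stages 3 and 4, and at 8.04 TPM at stage 5. Besides the 3 tags that led the steps into stage 3 and out of stage 4, they included CATGTGTTTTAGTCGTACGAG at 946 and 638 TPM and CATGGTGTGTCATAAGATGAG at 306 and 920 TPM, none of the 5 listed at stage 1 or stage 5. The same rule found 103 tags concentrated in stages 1 and 2, 33 in stages 4 and 5, and 5 in stages 2 and 3. Larger classes were concentrated in stages 1, 2 and 3 (324 tags) and in stages 3, 4 and 5 (143 tags), with 11 for stages 2, 3 and 4. The rule is relative to the peak, so such tags were not absent elsewhere. The 324 tags together stood at 1895 TPM at stage 4, and the 143 tags at 4059 TPM at stage 2. Tags concentrated in a single stage numbered 8, 4, 2, 3 and 5 from stage 1 to stage 5.

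From stage to stage, 1806 tags (8.39%) were higher each time and 1113 (5.17%) were lower each time, together 2919 tags (13.6%). These counts used library totals without TMM, took a difference of any size, and gave missing tags 1 copy. The trend test instead gave more falling than rising tags, 2611 and 1524 with TMM and 2133 and 1768 with library totals alone. The cause of this difference was not tested. The other orders of the 5 libraries gave up to 1687 such tags, with stages 1 and 2 exchanged, and 1651 with stages 4 and 5 exchanged. CATGTGGTGTACCATCCTGTA, among the 10 most abundant tags at stage 5, stood at 31.3, 66.9, 970, 3214 and 7881 TPM from stage 1 to stage 5. CATGAACTTGGGCTGTGCCAC, among the 10 most abundant at stage 1, stood at 3381, 2968, 913, 394 and 165 TPM. Of 10181 tags with a range of at least 4-fold, 26.7% peaked at stage 5 and 25.6% at stage 1, and 13.2% at stage 3.

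The trend and the large step from stage 2 to stage 3 were weighed against technical sources. The 4135 tags past the trend test exceeded the number in each of the other 59 orders of the 5 libraries, of which the highest gave 1704. Thus 1 of 60 orders gave as many, the smallest share that 60 orders can give. That argues against a chance order of the libraries but cannot exclude it. A technical drift in that same order cannot be excluded either. Removing differences between GC classes left 4491 trend tags and, for stage 3 against stage 2, 2760 tags past the size rule against 2743, which argues against a GC trend as the whole source although the mean GC content of the tags (17 bases after the site) was 37.4% at stage 1 and 34.3% at stage 5. A few abundant tags taking more of the copies would shift all other tags alike, and the median log2 ratio of all tags at that step was 0.0945, which argues against composition. Thinning to equal depth left 2719 tags but removed only 2.94% of the stage 3 library, so it tested nothing, as leaving the most abundant tags out of the totals moved the ratios by only 0.013 (log2). A difference between single libraries that has nothing to do with stage stays open for each step, as does the developmental difference itself, which was not tested against replicates.

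Many abundant tags came in pairs that differ at 1 base. Among the 5419 tags, 517 such pairs held 769 tags, and the minor tag had a median of 63.0% of the copies of the major one. In 162 of the pairs a member held a run of at least 8 A, which leaves few bases to tell transcripts apart, so these pairs are not read as alleles or gene copies. In the other 355, at the 99th percentile (0.486%) of all 1020 possible 1-base neighbours of the 20 most abundant tags, errors would bring a tag to 50 TPM from the major tag of 1 pair, which argues against sequencing errors if that rate holds for other tags. Their members' stage profiles lay closer (median distance 0.349 log2 units, 0.348 over all 517 pairs) than those of random pairs matched on abundance (1.00 to 1.18 in 95% of 10000 sets), which is consistent with shared control, as for alleles or close gene copies, between which the tags alone cannot decide. Of 2 earlier tests of errors, one found a copy ratio varying by more than 2-fold beyond counting error in 216 of the 517 pairs (41.8%), short of the majority set as its bound, and the other, on the share of the minor tag, was largely fixed by the 50 TPM limit and is not used.

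A second kind of pair, which overlaps the first in part, may mark the ends of transcripts. Of 498 tags at 10 TPM or more that ended in 6 or 7 A, 74 (14.9%, exact 95% interval 11.9% to 18.3%) shared their whole preceding start with a tag that continued differently, against 4.84% of 13460 tags not ending in A and compared at the same lengths, a ratio of 3.07. A candidate explanation is a poly(A) tail that begins inside the tag, so that 2 tags report 2 cleavage sites of one transcript. CATGCTTTTATGGCCAAAAAA had 22206 copies over the 5 libraries and its partner CATGCTTTTATGGCCTTTCCT had 5452, whereas over the 74 pairs the tag ending in A had a median of 23.5% of the copies of both. The control first chosen, tags ending in 6 or 7 T, held 17 tags of which 0 had such a partner, and could not be distinguished from the A tags (Fisher's exact test, two-sided, p = 0.15). Gene copies that differ at this place would look alike and stay open.

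Within the 17 bases after the site, CATG occurred in tags holding 0.617% of all copies, while the other 23 words of the same 4 bases were in tags holding 2.00% to 5.30%.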
